A study of Mus musculus with 12 samples.

How the data were processed

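Gene expression was measured by RNA-seq in 12 libraries of mouse embryonic fibroblasts, 3 for each combination of wild-type or CHIP-KO genotype with no heat or 1 hour at 43 °C. Per the labels' protocols, RNA was extracted from the cells and poly(A) RNA was captured for the libraries. The authors deposited 1 table of FPKM values (fragments scaled to gene length and library size) with 1 column per sample. Reads were aligned with HISAT2, per the submitters' processing notes; its version, the counting tool, the annotation and the library size used for scaling are not given in the sources used here. Group and replicate number were taken from the sample titles.

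The deposited FPKM values were checked for recoverable depth. Value times gene length was a whole multiple of 1 step per library for 100% of values above 0, within a tolerance of 0.01, which gave 15591924 to 26954112 fragments per library. FPKM times length in kilobases summed to 946546 to 1055290 per library, so the deposited scaling was not the sum over the listed genes. A value of 0 reads allows up to 3 reads, and such floors cover counting error only. Of 54532 gene identifiers, 54495 were in GENCODE M21 and 53548 of these had identical positions there, so positions are given on GRCm38. Replicates of a group differed by more than sampling noise (chi-square per degree of freedom 3.39 to 26.7 over genes with at least 20 reads in a pair), so none was counted as a repeat of another. Both wild-type replicates 1 stood apart: pairs with them gave 17.6 to 26.7 and the other wild-type pairs 3.49 and 5.09, and limma's library weights for them were 0.192 unheated and 0.165 heated. Among heated CHIP-KO libraries, pairs with replicate 1 gave 10.4 and 16.6 and the other pair 3.40. Principal components 1 and 2 of the log values held 40.0% and 36.4% of the variance.

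Genes with an FPKM of at least 1 in at least 3 of 12 libraries were kept, 13023 in all. Log2(FPKM + 1) was fitted with limma 3.58.1 in R 4.3.3, with a mean per group over all 12 libraries and a trend of variance on mean, so that the groups share 1 estimate of the spread. The contrasts were heat in each genotype, genotype at each treatment and their interaction, two-sided, called at a Benjamini-Hochberg adjusted p under 0.05. Before the data were examined, 36 gene lists were fixed, 28 of processes and 8 of cell type markers, and the 30 with at least 3 tested genes (all but 6) were tested with limma's camera at a preset correlation of 0.01, beside an estimated correlation. Named genes followed a rule fixed at the same time: protein-coding genes past the threshold, with a mean FPKM of at least 2 in the higher group and groups that do not overlap, the 10 largest rises and 10 largest falls per comparison, skipping predicted genes. For the interaction the overlap condition was not used. Stub1 and up to 4 members per list with the largest change were added. A gene that the rule names for the interaction is not reported here. Non-overlap of 3 against 3 arises in 10% of genes by chance. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

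The steps were tested on simulated data, drawn for the real genes and library sizes with 200 genes changed. All genes and libraries were given 1 dispersion of 0.01, a measure of spread beyond counting error. The real libraries spread unequally, with both wild-type replicates 1 apart, so the shares below hold for the simulated spread only. For heat in wild type (12624 genes), 53.8% of 1.5-fold, 91.0% of 2-fold and 98.4% of 4-fold changes were recovered. For the interaction (12595 genes) the shares were 18.8%, 65.2% and 96.8%. False calls made up 4.29% to 9.30% of calls over the 5 simulated comparisons, where 5% was the aim. Alternatives covered the pseudocount, the filter, scaling by median-of-ratios factors, quantiles or an equal sum per library, each pair of groups alone, library weights, the replicate number as a block, a minimum change and each library left out. Added after the data were seen were limma's voom on recovered fragments, protein-coding genes alone, thinning to equal depth, and leaving out wild-type replicates 1.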

Results

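RNA from mouse embryonic fibroblasts (MEFs, connective tissue cells cultured from mouse embryos) was sequenced in a design that crossed genotype with heat. Wild-type cells were compared with cells lacking CHIP, a ubiquitin ligase that works with chaperones and is encoded by Stub1, and each genotype was left unheated or held for 1 hour at 43 °C. Each of the 4 groups had 3 libraries, 12 in all. The fragments recovered from the table numbered 15591924 to 20098901 per library in unheated wild type and 17103444 to 19294361 in heated wild type. They numbered 22894580 to 26244726 in unheated CHIP-KO and 19953642 to 26954112 in heated CHIP-KO, so CHIP-KO libraries were mostly deeper, and the heated CHIP-KO range overlapped that of unheated wild type. Values are FPKM as mean ± SD over 3 libraries, fold changes are on the log2(FPKM + 1) scale, which understates the change of genes with low values, and adjusted p values are from limma with Benjamini-Hochberg adjustment over 13023 genes. The labels do not say whether the 3 libraries of a group came from separate cultures, so the p values measure only the spread between these samples, which may be technical.

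Stub1 (ENSMUSG00000039615, chromosome 17, positions 25830636 to 25833361, minus strand) was measured first, since its level checks the genotype labels. It stood at 61.7 ± 3.63 FPKM in unheated wild-type cells and 0.971 ± 0.229 FPKM in unheated CHIP-KO cells, 1.57% of wild type. After heat it stood at 55.4 ± 2.25 and 1.08 ± 0.0885 FPKM, so the CHIP-KO level was 1.94% of heated wild type. The libraries of replicates 1, 2 and 3 stood at 64.1, 63.4 and 57.5 FPKM in unheated and 54.4, 53.8 and 57.9 FPKM in heated wild type. The CHIP-KO libraries stood at 1.17, 1.02 and 0.722 FPKM unheated and 1.17, 0.996 and 1.06 FPKM heated. Each CHIP-KO library lay below each wild-type library, and the exact two-sided permutation test gave p = 0.1 for both treatments, the smallest p that 3 against 3 can give. Heat did not move Stub1 past the threshold in wild type (limma adjusted p = 0.132) or CHIP-KO (limma adjusted p = 0.539). With values scaled to an equal sum per library, Stub1 fell with heat in wild type at limma adjusted p = 0.0121. That scaling moved the median log2 change of all genes by -0.23 in this comparison, so the fall is not particular to Stub1.

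**Figure D1:**
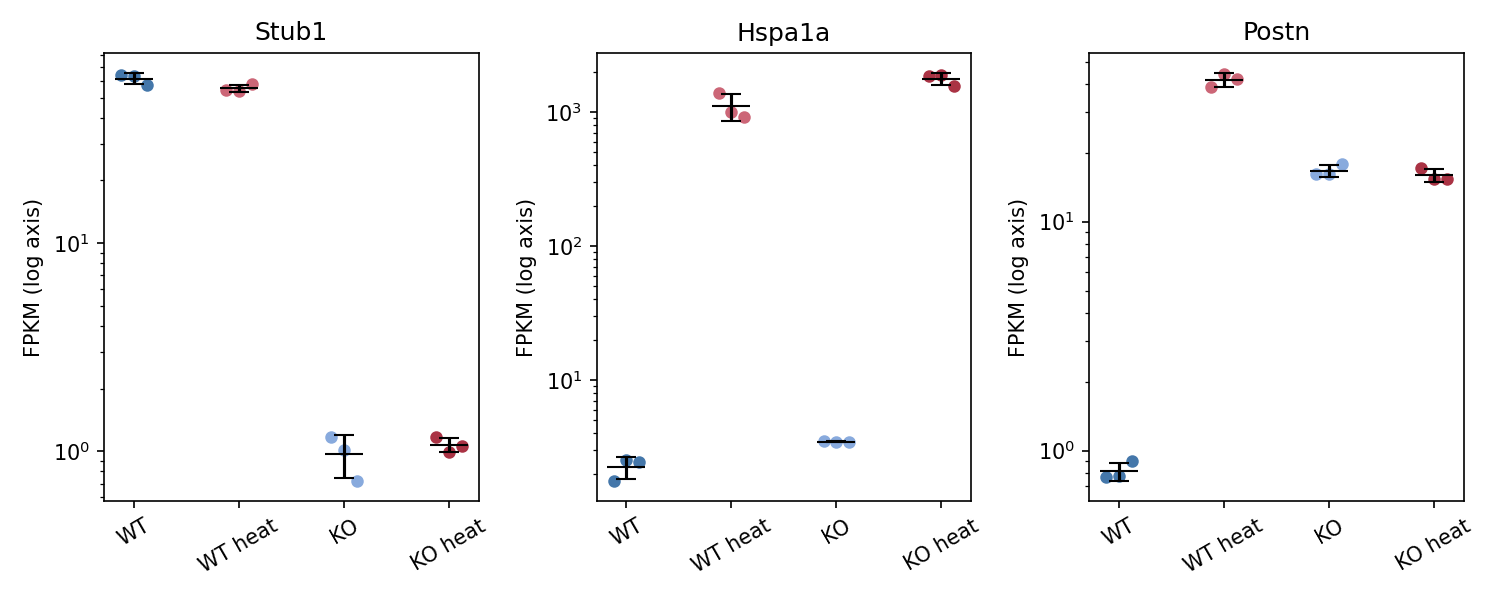
FPKM of Stub1, Hspa1a and Postn in each library (points) on log axes, with the mean and SD of each group of 3 libraries (black). Stub1 averaged 61.7 FPKM in unheated wild type and 0.971 in unheated CHIP-KO, Hspa1a rose with heat in both genotypes, and Postn went from 0.813 to 41.6 FPKM in wild type.

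The first comparison asked how wild-type fibroblasts respond to heat. Hspa1a (ENSMUSG00000091971, chromosome 17, positions 34969190 to 34972156, minus strand), an inducible HSP70 chaperone, rose from 2.25 ± 0.414 to 1104 ± 251 FPKM, 336-fold (limma adjusted p = 2.47e-11). Its near-identical copy Hspa1b rose 125-fold, and the split of reads between these paralogs is uncertain. The small heat shock protein gene Hspb1 rose 16.6-fold and the HSP40 co-chaperone gene Dnajb1 10.9-fold. Of 30 tested heat shock chaperones, 17 rose and 8 fell. For the heat shock chaperones list, camera gave adjusted p = 0.0342, and adjusted p = 0.648 with an estimated correlation, with 17 up and 8 down adjusted over the list alone. Immediate early genes, which respond quickly to many stimuli, rose in 23 of 27 cases. For the immediate early genes list, camera gave adjusted p = 1.15e-09, and adjusted p = 0.337 with an estimated correlation, with 23 up and 0 down adjusted over the list alone. Among them Atf3 rose 35.4-fold, Fos 29.1-fold, Egr1 25.9-fold and Jun 20.9-fold, and outside the list Phlda1 rose 23.7-fold. The nuclear receptor gene Nr4a1 rose 12.7-fold.

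Several groups fell in heated wild-type cells. Proteasome subunits fell in 30 of 31 cases, with Psmd6 at a log2 change of -0.93. For the proteasome subunits list, camera gave adjusted p = 1.15e-09, and adjusted p = 0.334 with an estimated correlation, with 0 up and 30 down adjusted over the list alone. The 8 subunits of the TRiC chaperonin, which folds actin and tubulin, all fell, with Cct6a at a log2 change of -1.06. For the TRiC chaperonin list, camera gave adjusted p = 4.43e-04, and adjusted p = 0.337 with an estimated correlation, with 0 up and 8 down adjusted over the list alone. ER chaperones fell in 17 of 20 cases, with Hspa5 at -0.95. For the ER chaperones list, camera gave adjusted p = 4.20e-05, and adjusted p = 0.334 with an estimated correlation, with 0 up and 17 down adjusted over the list alone. Cell cycle genes fell in 23 and rose in 2 of 32 cases, with cyclin D1 (Ccnd1) at -2.22, Rrm2 at -1.42 and Plk1 at -1.39. For the cell cycle list, camera gave adjusted p = 1.31e-06, and adjusted p = 0.334 with an estimated correlation, with 3 up and 23 down adjusted over the list alone. Of 17 genes of the integrated stress response, 9 fell and 4 rose. For the integrated stress response list, camera gave adjusted p = 0.0220, and adjusted p = 0.334 with an estimated correlation, with 4 up and 11 down adjusted over the list alone. Those that fell included the asparagine synthetase gene Asns (48.9 ± 10.2 to 8.74 ± 1.79 FPKM), the amino acid transporter gene Slc7a5 (69.9 ± 5.45 to 13.9 ± 0.759 FPKM), the serine synthesis gene Psat1 and Trib3. Ccnf fell from 31.6 ± 1.65 to 5.24 ± 0.726 FPKM, and Msln, Them6, Klra4 and Erfe were also among the 10 largest falls.

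Other groups rose in heated wild-type cells. Interferon response genes rose in 22 and fell in 1 of 23 cases, Usp18 4.44-fold and Irf7 3.94-fold. For the interferon response list, camera gave adjusted p = 3.86e-10, and adjusted p = 0.328 with an estimated correlation, with 22 up and 1 down adjusted over the list alone. Fibroblast and matrix genes rose in 16 and fell in 1 of 26 cases. For the fibroblast and matrix genes list, camera gave adjusted p = 2.31e-05, and adjusted p = 0.328 with an estimated correlation, with 16 up and 1 down adjusted over the list alone. Postn (ENSMUSG00000027750, chromosome 3, positions 54361109 to 54391037, plus strand), which encodes the matrix protein periostin, rose from 0.813 ± 0.0740 to 41.6 ± 2.83 FPKM, and Fn1 and Col3a1 rose 4.74-fold and 4.25-fold. The 5 tested cartilage and bone markers all rose, Sox9 6.86-fold and Comp 2.30-fold. For the cartilage and bone markers list, camera gave adjusted p = 0.00239, and adjusted p = 0.328 with an estimated correlation, with 5 up and 0 down adjusted over the list alone. BMP, TGF-beta and Notch early targets rose in 9 of 11 cases, Hes1 7.42-fold. For the BMP, TGF-beta and Notch early targets list, camera gave adjusted p = 6.15e-04, and adjusted p = 0.337 with an estimated correlation, with 9 up and 0 down adjusted over the list alone. Over all genes, 7640 of 13023 passed the test, 3664 higher and 3976 lower, and 854 rose and 222 fell at least 2-fold. With a mean FPKM of at least 5 required, 5087 genes passed, 2011 higher and 3076 lower, and with values scaled to an equal sum per library 2398 higher and 6155 lower. Without a filter the balance turned to 5379 higher and 3873 lower, and with median-of-ratios factors to 4022 higher and 3550 lower. The preset correlation called 18 of 30 lists and an estimated correlation 0 (3 at an unadjusted camera p under 0.05), while wrong groupings of these 6 libraries reached 14 with the preset value. A wrong grouping, here and below, mixes both real groups and keeps part of their difference, so its count is no measure of chance.

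The same question was asked of CHIP-KO fibroblasts. Hspa1a rose from 3.48 ± 0.0549 to 1769.7 ± 177 FPKM, 394-fold (limma adjusted p = 2.77e-11), Hspa1b 165-fold, Hspb1 17.3-fold and Dnajb1 14.5-fold. Heat shock chaperones rose in 22 and fell in 1 of 30 cases. For the heat shock chaperones list, camera gave adjusted p = 6.79e-18, and adjusted p = 0.285 with an estimated correlation, with 24 up and 1 down adjusted over the list alone. Immediate early genes rose in 21 of 27 cases, Atf3 35.1-fold, Jun 18.5-fold and the phosphatase gene Dusp1 12.4-fold. For the immediate early genes list, camera gave adjusted p = 2.46e-20, and adjusted p = 0.285 with an estimated correlation, with 24 up and 0 down adjusted over the list alone. Phlda1 rose 23.7-fold and the BMP antagonist gene Nog 13.4-fold, and Arc was also among the 10 largest rises. Ccnf fell from 24.3 ± 0.543 to 7.14 ± 1.00 FPKM, Ap5b1 from 6.22 ± 0.197 to 1.76 ± 0.149 FPKM and Fam222b from 13.6 ± 0.349 to 4.76 ± 0.481 FPKM. The other genes among the 10 largest falls were Ttc30b, Lcmt2, Hps6, Pcyox1l, Zcchc3, Hdhd3 and Efna4.

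Proteasome subunits gave 0 rises and 0 falls past the limma threshold among 31 genes in heated CHIP-KO cells, with 4 and 0 at an unadjusted p under 0.05 and a median log2 change of 0.10. For the proteasome subunits list, camera gave adjusted p = 0.0178, and adjusted p = 0.685 with an estimated correlation, with 0 up and 0 down adjusted over the list alone. Interferon response genes fell in 10 and rose in 2 of 23 cases, with Ifit3 at a log2 change of -0.92 and Ifit1 at -0.83. For the interferon response list, camera gave adjusted p = 4.05e-04, and adjusted p = 0.528 with an estimated correlation, with 2 up and 15 down adjusted over the list alone. Cytosolic ribosomal proteins rose in 21 of 38 cases at a median log2 change of 0.28, which turned to -0.0063 under quantile normalization. For the cytosolic ribosomal proteins list, camera gave adjusted p = 4.39e-12, and adjusted p = 0.285 with an estimated correlation, with 33 up and 0 down adjusted over the list alone. Of fibroblast and matrix genes, 2 rose and 1 fell among 26. For the fibroblast and matrix genes list, camera gave adjusted p = 0.152, and adjusted p = 0.528 with an estimated correlation, with 0 up and 0 down adjusted over the list alone. Their median log2 change of 0.089 turned to -0.089 under quantile normalization, and Postn stood at 16.7 ± 0.969 FPKM before and 15.9 ± 1.02 FPKM after heat. In all, 2607 genes passed, 1126 higher and 1481 lower, and 326 rose and 29 fell at least 2-fold. This count was 1687, 1627 and 1592 without CHIP-KO unheated replicates 1, 2 and 3, 1578 with a mean FPKM of at least 5, 4043 with these groups alone, 6201 with library weights, 4414 without both wild-type replicates 1, which stood apart from the other replicates of their groups, and 8711 (585 higher and 8126 lower) with values scaled to an equal sum. Without a filter the balance turned, with slightly more genes higher than lower. The preset correlation called 13 of 30 lists and an estimated correlation 0 (5 at an unadjusted camera p under 0.05), quantile normalization left 6, and wrong groupings of these libraries reached 8.

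The heat responses were then compared across genes. Their log2 changes correlated across 13023 genes at Pearson r = 0.586 and Spearman rho = 0.374, with a slope of 0.393 for CHIP-KO on wild type; genes are not independent replicates. Genes higher after heat in both genotypes numbered 777, against 317 for independent lists, and those lower in both 876 against 452. Genes that moved in opposite directions numbered 218 higher in wild type and lower in CHIP-KO, and 115 the other way.

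**Figure D2:**
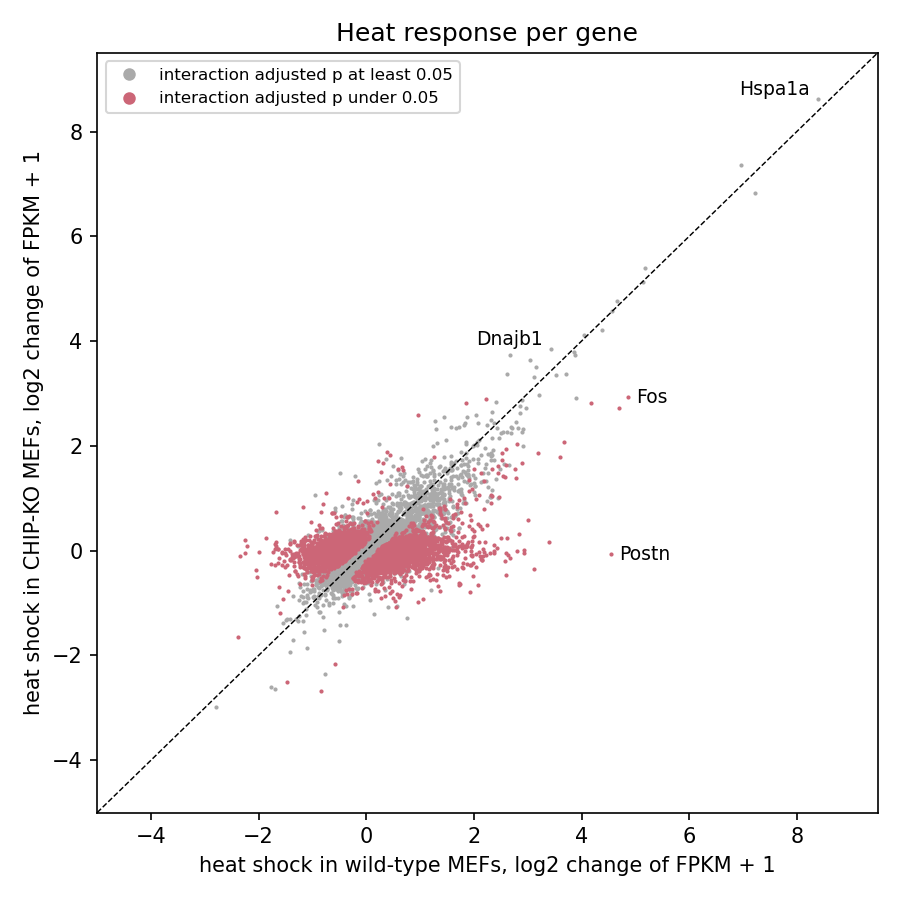
Log2 change of FPKM + 1 with heat in wild-type (horizontal) and CHIP-KO (vertical) fibroblasts, 1 point per gene, with the dashed line of equal change. Genes whose change differed between genotypes (interaction adjusted p under 0.05, 4581 genes) are red; Hspa1a lies near the line and Postn far below it.

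The interaction term tested directly whether the change with heat differed between genotypes. Among genes named by the rule Postn had the largest interaction, a log2 change of -4.61 (SE 0.0954, limma adjusted p = 5.88e-10). Proteasome subunits changed more positively in CHIP-KO in 29 of 31 cases, Psmc4 by 0.89 and Psmd2 by 0.88. For the proteasome subunits list, camera gave adjusted p = 1.37e-13, and adjusted p = 0.227 with an estimated correlation, with 29 up and 0 down adjusted over the list alone. The 8 TRiC subunits did likewise, Cct6a by 1.14. For the TRiC chaperonin list, camera gave adjusted p = 1.01e-05, and adjusted p = 0.284 with an estimated correlation, with 8 up and 0 down adjusted over the list alone. Cell cycle genes did in 20 of 32 cases, Ccnd1 by 2.31 (camera adjusted p = 5.22e-08, adjusted p = 0.224 with an estimated correlation, 22 up and 2 down adjusted over the list alone), and integrated stress response genes in 11 of 17, Asns by 2.26. For the integrated stress response list, camera gave adjusted p = 9.02e-05, and adjusted p = 0.188 with an estimated correlation, with 11 up and 3 down adjusted over the list alone. Heat shock chaperones did in 14 of 30 cases, Hsp90aa1 by 0.98 and Hspd1 by 0.97. For the heat shock chaperones list, camera gave adjusted p = 1.69e-04, and adjusted p = 0.457 with an estimated correlation, with 16 up and 1 down adjusted over the list alone. Interferon response genes went the other way in 22 of 23 cases, Irf7 at -2.45 and Usp18 at -2.33. For the interferon response list, camera gave adjusted p = 3.67e-15, and adjusted p = 0.188 with an estimated correlation, with 1 up and 22 down adjusted over the list alone. Matrix genes did in 13 of 26, Col3a1 at -2.11 and Fn1 at -1.75. For the fibroblast and matrix genes list, camera gave adjusted p = 1.51e-05, and adjusted p = 0.188 with an estimated correlation, with 1 up and 13 down adjusted over the list alone. The cartilage and bone markers did in 5 of 5, at a median log2 change of -0.85 (camera adjusted p = 0.00222, adjusted p = 0.188 with an estimated correlation, 0 up and 5 down adjusted over the list alone). Among immediate early genes 9 of 27 had a negative and 0 a positive interaction, Egr1 at -1.96 and Fos at -1.93, and both were higher in unheated CHIP-KO cells. For the immediate early genes list, camera gave adjusted p = 0.0504, and adjusted p = 0.774 with an estimated correlation, with 0 up and 9 down adjusted over the list alone. The interaction passed for 4581 genes, 2328 positive and 2253 negative, with 173 positive and 420 negative at least 2-fold. With values scaled to an equal sum 1739 higher and 2833 lower passed, against 2015 higher and 1403 lower with a mean FPKM of at least 5. Library weights gave 7403 genes. The preset correlation called 20 of 30 lists and an estimated correlation 0 (5 at an unadjusted camera p under 0.05). Of the 4581 genes, 3484 had a called heat change in wild type alone, 254 in CHIP-KO alone, 354 in both with the same sign, 333 in both with opposite signs and 156 in neither.

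Genotypes were next compared without heat. All 23 tested interferon response genes were higher in CHIP-KO cells, Usp18 at 51.5 ± 1.92 against 1.68 ± 0.209 FPKM, Ifit3 at 109.9 ± 3.68 against 5.61 ± 1.25 FPKM. For the interferon response list, camera gave adjusted p = 8.01e-22, and adjusted p = 0.0400 with an estimated correlation, with 23 up and 0 down adjusted over the list alone. Fibroblast and matrix genes were higher in 21 and lower in 3 of 26 cases. For the fibroblast and matrix genes list, camera gave adjusted p = 1.84e-10, and adjusted p = 0.0303 with an estimated correlation, with 21 up and 3 down adjusted over the list alone. The matrix metalloproteinase gene Mmp2 stood at 83.5 ± 4.28 against 2.38 ± 0.254 FPKM, the collagen gene Col1a2 was 14.2-fold and the receptor gene Pdgfra 10.1-fold higher. All 20 tested genes of cholesterol synthesis were lower, Mvd at a log2 change of -1.41, Msmo1 at -1.37 and Sqle at -1.21. For the cholesterol synthesis list, camera gave adjusted p = 4.55e-11, and adjusted p = 0.0303 with an estimated correlation, with 0 up and 20 down adjusted over the list alone. Proteasome subunits were lower in 26 and higher in 1 of 31 cases (camera adjusted p = 4.99e-07, adjusted p = 0.397 with an estimated correlation, 1 up and 28 down adjusted over the list alone) and the 8 TRiC subunits in all. For the TRiC chaperonin list, camera gave adjusted p = 6.89e-04, and adjusted p = 0.397 with an estimated correlation, with 0 up and 8 down adjusted over the list alone. Heat shock chaperones were lower in 17 and higher in 4 of 30 cases, with Hspb8 at 11.4 ± 0.650 against 69.0 ± 1.06 FPKM. For the heat shock chaperones list, camera gave adjusted p = 0.00135, and adjusted p = 0.518 with an estimated correlation, with 4 up and 17 down adjusted over the list alone. NRF2 targets, which protect against oxidants, were lower in 12 and higher in 1 of 20 cases, Gclc at -1.01 and Gclm at -0.84. For the NRF2 targets list, camera gave adjusted p = 2.72e-04, and adjusted p = 0.188 with an estimated correlation, with 1 up and 12 down adjusted over the list alone. Immediate early genes were higher in 14 of 27 cases, Egr1 5.25-fold and Fos 3.74-fold. For the immediate early genes list, camera gave adjusted p = 0.00336, and adjusted p = 0.557 with an estimated correlation, with 14 up and 0 down adjusted over the list alone.

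Genes of position and origin also differed. Hox genes, which mark position along the body, were higher in 17 and lower in 5 of 27 cases, Hoxc6 at a log2 change of 3.49. For the Hox genes list, camera gave adjusted p = 2.72e-04, and adjusted p = 0.214 with an estimated correlation, with 17 up and 5 down adjusted over the list alone. Hoxc8 had 0 reads in unheated wild type and was at least 336-fold higher in CHIP-KO. The hindlimb transcription factor gene Pitx1 stood at 40.8 ± 2.41 FPKM in wild type and had 0 reads in the 3 CHIP-KO libraries, at least 2733-fold lower against a floor of 3 reads over the group. Imprinted genes were higher in 7 of 10 cases (camera adjusted p = 6.89e-04, adjusted p = 0.0981 with an estimated correlation, 7 up and 0 down adjusted over the list alone), and Dlk1 had 0 reads in wild type and 17.8 ± 0.217 FPKM in CHIP-KO, at least 1895-fold higher. The Y-linked genes Ddx3y, Eif2s3y and Kdm5d had 0 reads in every wild-type library and were at least 1386-fold, 1042-fold and 779-fold higher in CHIP-KO, while the Y-linked gene Uty had 381 to 553 reads per wild-type and 560 to 773 per CHIP-KO library. Enpp2, Efemp1, Angptl4, Gbp2, Ltbp2 and Gbp3 were also among the 10 largest rises. Megf6 stood at 1.05 ± 0.0962 against 30.8 ± 1.56 FPKM, and Lmcd1, Aqp5, Stat6, Cadm1, Ripk3 and Csf2ra were among the 10 largest falls beside Stub1. In all, 6311 genes passed, 3117 higher and 3194 lower in CHIP-KO, and 614 and 200 differed at least 2-fold. The balance turned to 3489 higher and 3080 lower without a filter, 3302 higher and 2967 lower with an equal sum and 3215 higher and 3096 lower with median-of-ratios factors. The preset correlation called 19 of 30 lists and an estimated correlation 4 (7 at an unadjusted camera p under 0.05), and wrong groupings reached 15. The calls that held were matrix, interferon, cholesterol synthesis and the sex-linked markers, of which 3 of 4 were higher. For the sex-linked marker genes list, camera gave adjusted p = 1.36e-04, and adjusted p = 0.0303 with an estimated correlation, with 4 up and 0 down adjusted over the list alone.

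Genotypes were compared after heat as well. Of 23 interferon response genes 22 were higher in CHIP-KO, Rsad2 4.73-fold and Ifit3 4.35-fold. For the interferon response list, camera gave adjusted p = 2.52e-15, and adjusted p = 0.0991 with an estimated correlation, with 23 up and 0 down adjusted over the list alone. Cholesterol synthesis genes were lower in 19 of 20 cases, Hmgcs1 at -1.23 and Mvd at -1.22. For the cholesterol synthesis list, camera gave adjusted p = 1.30e-11, and adjusted p = 0.0539 with an estimated correlation, with 0 up and 19 down adjusted over the list alone. Proteasome subunits were higher in 20 of 31 cases (camera adjusted p = 8.68e-05, adjusted p = 0.468 with an estimated correlation, 22 up and 0 down adjusted over the list alone), and integrated stress response genes in 11 of 17, Slc7a5 4.05-fold and Asns 3.84-fold. For the integrated stress response list, camera gave adjusted p = 6.24e-04, and adjusted p = 0.216 with an estimated correlation, with 11 up and 2 down adjusted over the list alone. Cell cycle genes were higher in 19 and lower in 2 of 32 cases. For the cell cycle list, camera gave adjusted p = 0.00103, and adjusted p = 0.442 with an estimated correlation, with 20 up and 2 down adjusted over the list alone. Of 30 heat shock chaperones 8 were higher and 3 lower, Dnajb1 1.81-fold higher and Hspb8 at -2.02. For the heat shock chaperones list, camera gave adjusted p = 0.302, and adjusted p = 0.889 with an estimated correlation, with 8 up and 3 down adjusted over the list alone. Dlk1, Ddx3y and Eif2s3y, at 0 reads in heated wild type, were at least 2092-fold, 1327-fold and 1123-fold higher, and Pitx1 at least 2777-fold lower. Wnt10a, Hoxc6 and Col1a2 were also among the 10 largest rises, and Megf6, Gas6, Sfrp2, Gpnmb, Rasl11a and Ephb6 among the 10 largest falls. Gas6 went from 3.54 ± 0.593 to 16.5 ± 1.15 FPKM with heat in wild type and stood at 0.0392 ± 0.0384 FPKM in heated CHIP-KO cells. In all, 5525 genes passed, 3033 higher and 2492 lower (361 and 282 at least 2-fold), and with values scaled to an equal sum 2366 higher and 3038 lower. Library weights gave 8590 genes. The preset correlation called 15 of 30 lists and an estimated correlation 0 (5 at an unadjusted camera p under 0.05), and wrong groupings reached 12.

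**Figure D3:**
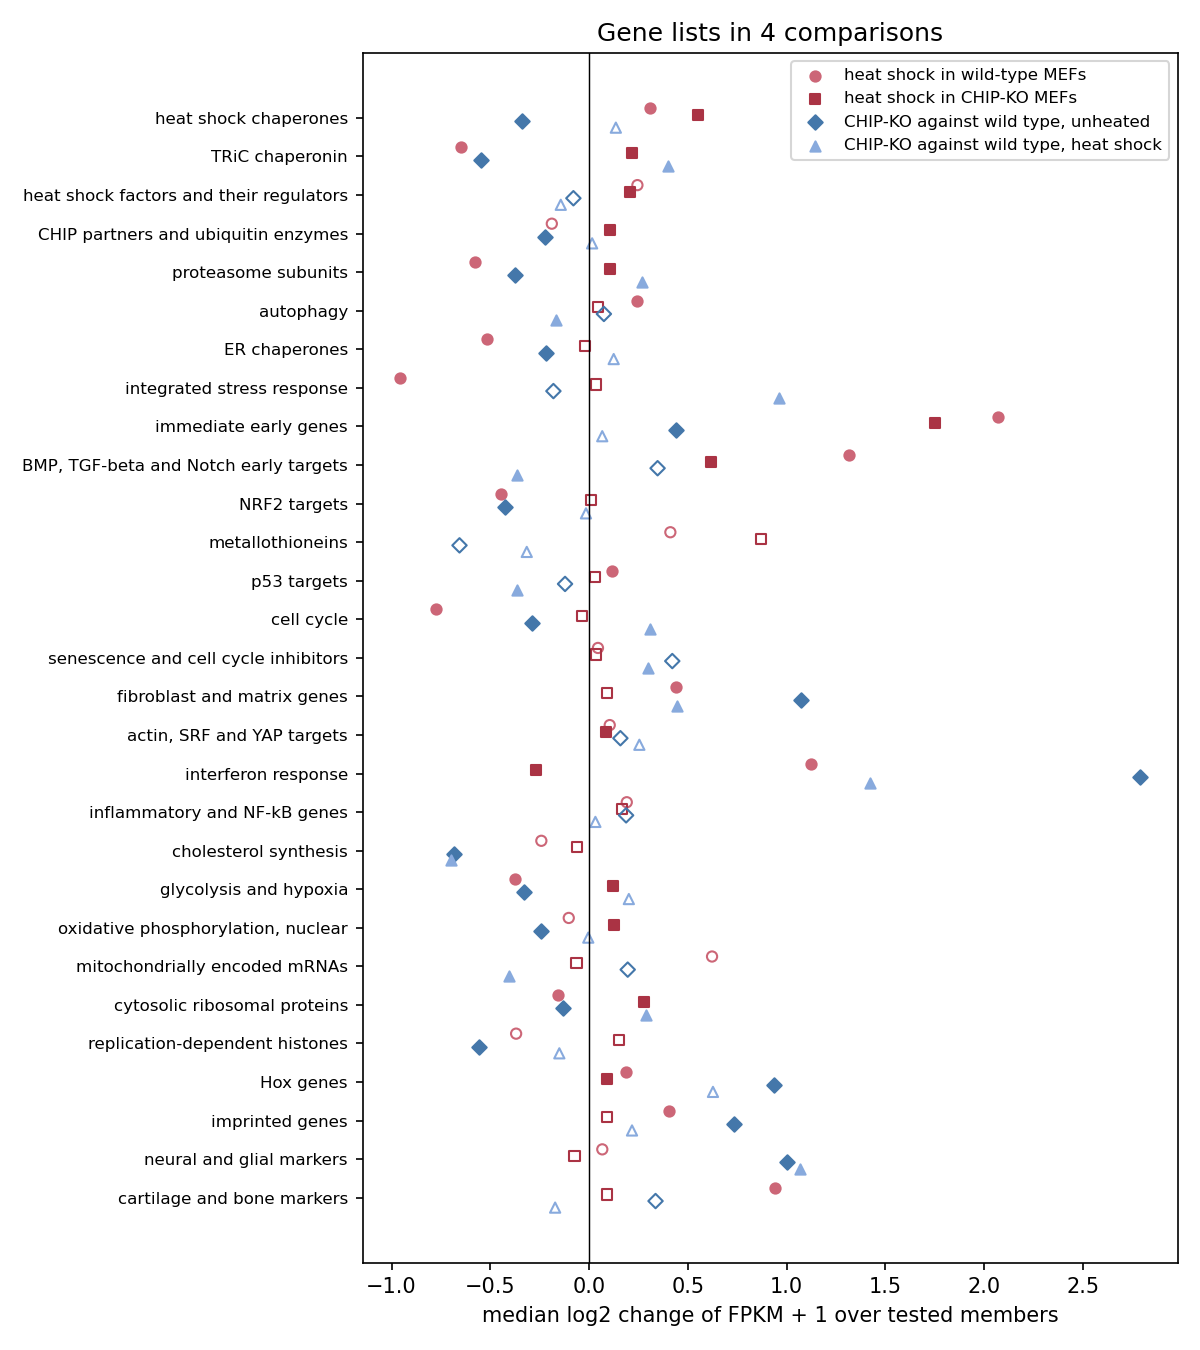
Median log2 change of FPKM + 1 over the tested members of each of 29 gene lists in 4 comparisons, without the sex-linked markers, most of which had 0 reads in wild type; filled markers have a camera adjusted p under 0.05 at a preset correlation of 0.01, open markers do not. Interferon response genes lie at 2.79 for CHIP-KO against wild type without heat, and under quantile normalization the sign of the median turned for 9 lists with heat in CHIP-KO and 3 in wild type.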

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

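The tests of left-out libraries, depth, growth state, Y-linked genes and the other genes outside the Y chromosome were chosen after the values they use had been seen; the Stub1 segment and the regroupings of libraries were planned before. The change with heat differed between genotypes, by the interaction term, for 4581 genes and 20 gene lists. The 10 largest positive interaction log2 changes were Msln 2.46, Krt19 2.40, Ccnd1 2.31, Asns 2.26, Slc7a5 2.20, Ankrd1 2.02, Psat1 1.97, F2rl1 1.82, Hmga1 1.76, Tmem238 1.72. Among the largest negative were Postn -4.61, Plxdc2 -3.47, Mgp -3.22, Ifi27l2a -3.07, Serpinf1 -2.98, Fmod -2.82, Nov -2.78, Islr -2.75, Txnip -2.72.

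This difference between genotypes did not rest on a single library or on depth: the lowest interaction count with 1 library left out was 3793 and the count after thinning to equal depth 4370. Of 593 interaction genes of at least 2-fold, 60.9% had the unheated CHIP-KO mean nearer to heated than to unheated wild type, and the group farthest from the others was unheated wild type for 323 and heated wild type for 228. Unheated wild-type cultures in another growth state would give that share but not, by themselves, those 228 genes, and loss of CHIP acting on unheated cells predicts the same share, so a culture difference behind part of the genes and an effect of CHIP both stay open. When heat groups were redrawn within genotypes, 5 of 100 splits, the real one included, gave at least 4581 genes and the highest other gave 4974. Redrawing within genotypes decides nothing about chance here, since a split that keeps the wild-type heat groups and mixes CHIP-KO turns the wild-type heat change into an interaction by construction: all 5 kept those groups, the 9 splits that did so gave 3526 to 4974 genes, and the 91 that mixed them gave at most 2.

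For the 20 interaction lists, 2 of 100 splits gave as many, the highest other giving 20, which decides nothing about chance for the same reason. In each 3 against 3 comparison 1 of 10 splits, the real one, was as large, and 10 splits are too few for a share under 0.05. The real and highest other counts were 7640 and 0 genes for heat in wild type, 2607 and 1 for heat in CHIP-KO, 6311 and 0 for genotype without heat and 5525 and 3 with heat. For lists they were 18 and 14, 13 and 8, 19 and 15, and 15 and 12. Wrong groupings that called at most 3 genes called up to 15 lists. Each of them mixes libraries of both real groups, so it keeps part of their real difference and widens the spread within groups. Their gene and list counts are thus no baseline for chance. A list count at the preset correlation is to be read only beside that with an estimated correlation.

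The second pattern weighed was the difference in Y-linked, Hox, Pitx1 and imprinted genes between genotypes. All 3 of Ddx3y, Eif2s3y and Kdm5d had 0 reads in every wild-type and over 3 in every CHIP-KO library, which cells from different embryos or lines can give, while 381 to 553 reads of Uty per wild-type library (CHIP-KO 560 to 773) go against loss or absence of all Y-linked genes, unless they stem from its X-linked copy. Of the 5 listed sex-linked genes, Xist among them, 4 were tested and 0 were called lower in CHIP-KO without heat. The listed gene that was not tested reached an FPKM of 1 in fewer than 3 of 12 libraries, and such a gene cannot be called. If it was Xist, its missing call came from the filter and is no comparison of genotypes. Either way, these values do not show female wild-type cells. For the 6307 genes called outside the Y chromosome, origin and loss of CHIP cannot be told apart, because the design holds no second pair of lines. A segment of chromosome 17 carried along with the knockout cannot hold the Y-linked genes. Within 5 Mb of Stub1 lay 101 called genes, and 6209 lay elsewhere. These counts were fixed by the size of the window: with only 183 tested genes there, no such segment could hold most of the called genes. Whether it changed genes near Stub1 was not decided: 55.2% of 183 genes were called there against 48.4% elsewhere (odds ratio 1.32, 95% interval 0.971 to 1.79, Fisher exact two-sided p = 0.0737). Of 405 windows of 5 Mb over the genome, 112 had as high a share. These windows spanned 5 Mb in all and needed only 10 tested genes, while the Stub1 region reached 5 Mb to each side. The shares are thus not compared on equal terms.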

How the results depend on the processing

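Voom, protein-coding genes alone, thinning to equal depth, wild-type replicates 1 left out, and the refits of list counts, Stub1, the correlation and named genes under settings planned for gene counts alone were chosen after seeing the data. Gene and list counts stayed within 1.5 times their value under the alternatives run, apart from those given here, and the cause was not tested unless stated. A mean FPKM of at least 5 gave 5087 genes for heat in wild type and 1578 for heat in CHIP-KO, from fewer genes tested. A minimum change of 1 on the log2 scale gave, by its construction, 1076, 355, 814, 643 and 593 for heat in wild type, heat in CHIP-KO, genotype without heat, genotype with heat and the interaction. Heat in CHIP-KO was the least stable count: 4043 with its groups alone, 6201 with library weights, 4414 without wild-type replicates 1, which stood apart from the others, and 8711 (585 higher and 8126 lower) with an equal sum per library. That scaling moved the median of all genes by -0.23 for heat in wild type and -0.33 in CHIP-KO. Which direction held more genes turned with the setting in all 5 comparisons: without a filter, 5379 higher and 3873 lower for heat in wild type, 1277 higher and 1233 lower for heat in CHIP-KO, 3489 higher and 3080 lower for genotype without heat and 1995 higher and 2262 lower for the interaction, and with an equal sum 2366 higher and 3038 lower for genotype with heat. Library weights also gave 8590 for genotype with heat and 7403 for the interaction. With 1 library left out, heat in CHIP-KO ranged from 1592 to 3462, with 1687, 1627 and 1592 without CHIP-KO unheated replicates 1, 2 and 3. The ranges were 7033 to 7622 for heat in wild type, 5325 to 6853 and 4635 to 6042 for genotype without and with heat and 3793 to 4870 for the interaction. The correlation of the heat responses, 0.586, was 0.647 with a pseudocount of 0.1, 0.632 with an equal sum, 0.539 with library weights, 0.652 with voom and 0.503 over protein-coding genes alone. Lists called with an estimated correlation numbered 0, 0, 4, 0 and 0 in the same order of comparisons, and quantile normalization left 6 for heat in CHIP-KO. The Stub1 odds ratio within 10 Mb was 1.02. Of 4588 refits of 182 named gene values, 0 reversed, 8 lost their call, all of them Rpl7a with heat in CHIP-KO, and 1 gained one, Stub1 with heat in wild type under an equal sum. A change of sign counted as a reversal only where the main fit had called the gene. Many of these genes were named for large called changes in these same data, so their stability says little about other calls. The interaction with groups compared alone was not run, since it needs all 4 groups.

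With the replicate number as a block, the counts were 7637, 2606, 6299, 5525 and 4583 genes and 19, 12, 19, 14 and 21 lists, and within genotype 7166, 1988 and 3886 genes for both heat comparisons and the interaction. Most samples with the same number did not deviate together (2 of 18 correlations above 0.1, range -0.12 to 0.33, own number best in 4). Both correlations above 0.1 were between heated wild type and heated CHIP-KO, 0.33 for replicates 1 and 0.23 for replicates 3. For replicates 2 of these groups it was 0.021. Heated samples of the same number may thus share more than a number, which the labels do not state. At these library sizes and the assumed dispersion of 0.01, a 1.5-fold interaction was recovered in 18.8% of simulated genes.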

Other observations

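Tests of the poly(A) selection and depth explanations were chosen after the values had been seen. The predictions on single-exon and downstream noncoding genes were written before their tests ran, but both start from patterns in these same data. Several noncoding RNAs, among them RNAs without long poly(A) tails, rose with heat. Gm26917, annotated as a long noncoding RNA, went from 42.9 ± 8.62 to 1578 ± 278 FPKM in wild type and from 36.3 ± 6.02 to 1578 ± 289.9 in CHIP-KO. The small nuclear RNA gene Rn7sk rose 14.5-fold and 13.9-fold, and the mitochondrial ribosomal RNAs mt-Rnr1 and mt-Rnr2 went from 123 to 751 and from 249 to 1249.5 FPKM in wild type, and rose 4.83-fold and 3.62-fold in CHIP-KO. These genes fall outside the naming rule and were chosen after their values were seen. Mitochondrial ribosomal RNA made up 0.0531% of fragments in unheated and 0.272% in heated wild type. Autophagy genes rose in 13 and fell in 3 of 21 cases with heat in wild type, Lamp2 2.14-fold and Map1lc3b 2.04-fold. For the autophagy list, camera gave adjusted p = 0.0102, and adjusted p = 0.334 with an estimated correlation, with 13 up and 3 down adjusted over the list alone. Neural and glial markers were higher in CHIP-KO without heat in 3 of 4 cases, Sox2 3.79-fold and Tubb3 2.14-fold. For the neural and glial markers list, camera gave adjusted p = 0.0307, and adjusted p = 0.193 with an estimated correlation, with 3 up and 1 down adjusted over the list alone. With heat 4 of 4 were higher (camera adjusted p = 0.00209, adjusted p = 0.0842 with an estimated correlation, 4 up and 0 down adjusted over the list alone).

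After thinning to equal depth, the smallest log2 change among Gm26917, Rn7sk, mt-Rnr1 and mt-Rnr2 was 1.86. Thinned values were scaled back to library size, which leaves the expected level of a transcript unchanged, so thinning could not decide whether depth gave their rise. Less complete poly(A) selection in heated libraries would raise replication-dependent histone mRNAs as well, yet their median log2 change with heat in CHIP-KO was 0.15 (SD 0.41 over 11 genes) against a smallest rise of 1.86 among Gm26917, Rn7sk, mt-Rnr1 and mt-Rnr2. This argues against it as the whole cause only if heat left the histone mRNAs themselves unchanged, which was not tested. Part of the histone reads may also come from polyadenylated forms. A change in these transcripts or their tails with heat may remain as a hypothesis, found and tested on the same data.

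It was predicted that noncoding genes starting within 10 kb downstream of a tested gene would rise with heat in CHIP-KO through transcription past gene ends. The difference in medians was -0.0598 on the log2 scale (227 against 1752 genes, permutation p = 0.134), which goes against it there. In wild type, for which no prediction was made, the difference was 0.15 (permutation p = 0.00535).

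Single-exon genes were predicted to fall more often with heat in CHIP-KO. The prediction started from genes that fell with heat in these data, so the CHIP-KO test is not independent of it. Of 244 such genes 22.1% fell, against 12.4% of 10762 with several exons (odds ratio 2.01, 95% interval 1.45 to 2.75, Fisher exact two-sided p = 3.33e-05), and they also rose more often, 11.9% against 7.07%. In wild type the shares that fell were 34.0% and 34.3%, yet the median log2 change of single-exon genes, -0.10, lay below that of the others there too (-0.038), as in CHIP-KO (-0.048 against -0.013). Low expression did not account for the lower medians, since 0.01% in wild type and 0.06% in CHIP-KO of 10000 random lists matched on expression had as low a median. Other causes were not tested.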
